A study of Caenorhabditis elegans with 12 samples.

How the data were processed

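Each of the 12 libraries came from 800 adult animals raised from embryos for 72 h at 25 °C on RNAi bacteria, with RNA isolated by Qiazol and column purification with DNase and selected for poly(A), per the labels' protocols. The animals carried glp-1(e2144) with wild-type hoe-1 or with hoe-1(ΔNES), written hoe-1(mpt67) in the sample titles, and were fed control or atfs-1 RNAi, which makes 4 groups of 3 biological replicates. The submitters' processing notes name FastQC, Trimmomatic 0.39, STAR 2.5.4, Salmon and DESeq2, without a role or order for each. The versions of Salmon, FastQC and DESeq2 and the genome build and annotation behind the quantification are not given in the sources used here.

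The deposited files hold 1 Salmon table per library. Per the file headers the columns are expected counts (Salmon's estimated number of reads per transcript), TPM and the transcript length and effective length in bases, each for 34526 transcripts. In the deposited files a share of 33.2% to 40.4% of the transcript counts had a decimal part other than exactly 0, and the totals ran from 25733083 to 41357645 per library. TPM was used to weight the average effective length of each gene, and effective length entered the tests only in 1 alternative.

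Transcripts were assigned to genes with the Ensembl 115 annotation of WBcel235, and every transcript matched. Expected counts were summed per gene over 21978 genes (19889 protein-coding and 2089 pseudogenes) and rounded. The tables had no entry for 96 annotated protein-coding genes, and 24 genes share their symbol with another gene and were kept apart by their identifiers. Replicates of the same group correlated with a Spearman rho of 0.9872 to 0.995 across genes, and no pair of libraries was a duplicate. Replicate numbers were tested for pairing of samples across groups. The residuals of libraries with the same number correlated between -0.107 and 0.158 (median 0.0455, 3 of 18 pairs above 0.1), so no pairing term was fitted.

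Genes were tested with edgeR 4.0.16 under R 4.3.3, after filterByExpr with a minimum count of 10 and a minimum total of 15, which left 13947 genes. TMM factors ran from 0.866 to 1.108. A quasi-likelihood model with robust estimation and 1 mean per group was fitted to the 12 libraries together (common biological coefficient of variation 0.121). The 5 contrasts were hoe-1(ΔNES) against wild type on control RNAi and on atfs-1 RNAi, atfs-1 against control RNAi in wild type and in hoe-1(ΔNES), and the interaction of genotype and RNAi. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 per contrast. SEs of log2 fold changes come from the same model. A group with 0 counts was given a floor of 3 counts over its libraries (0.0257 to 0.0359 CPM), and no fold is given as a bound for groups with 1 to 3 counts.

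Before the data were examined, 33 gene lists were fixed from general knowledge of C. elegans. Each list was tested per contrast with camera in limma 3.58.1 at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over 165 tests, of which 66 were called. With the correlation estimated per list 4 calls held, namely the mitochondrial chaperones on control RNAi, for atfs-1 RNAi in hoe-1(ΔNES) and for the interaction, and the propionate list for atfs-1 RNAi in wild type. A list's count adjusted over the list alone applies the Benjamini-Hochberg step to its members only. The lists overlap in a few members such as cyp-14A4 and sqst-1.

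Genes are named by a rule that was fixed with the lists. It takes atfs-1, hoe-1, hsp-6 and hsp-60 in every contrast. It also takes the 10 largest increases and 10 largest decreases on control RNAi, or 6 and 6 in the other contrasts, among called genes with an average log2 CPM of at least 1 and, outside the interaction, no overlap of the groups. From each list described it takes up to 4 called members with the smallest adjusted p. Genes outside the rule are said to have been chosen after their values were seen.

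The procedure was tested on simulated data with the depth and spread of these libraries. A log2 change of 1 was recovered for 71.2% of simulated genes in the contrast on control RNAi, 71.6% on atfs-1 RNAi, 80.3% and 68.7% for atfs-1 RNAi in wild type and in hoe-1(ΔNES), and 54.5% for the interaction. False calls made up 3.9%, 3.9%, 4.8%, 7.3% and 7% of the calls. Changes of 0.5 were recovered for 4.6% to 40.9%, so small changes that were not called may be below what 3 libraries per group can resolve. The simulations changed far fewer genes than the data, for example 66 of 13625 by a log2 change of 1 on control RNAi, where the data called 6110. With few changed genes the adjusted threshold is stricter, so these recovered shares may be too low for the data. In 10 simulations without an interaction, the genes called on control RNAi and their medians on either RNAi were recorded as the baseline for the dependence on atfs-1.

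Alternatives tried were the DESeq2 1.42.0 Wald test, RLE size factors, total counts alone, no filter, a stricter filter of 5 CPM in 3 libraries, an effective length offset, a replicate block, fits with only the groups compared, fry and an estimated correlation for the lists, and leaving out each of the 12 libraries in turn. Leaving the vitellogenin genes out of the scaling was added after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Raw reads were not analysed here, so the hoe-1 allele itself and the source of reads shared by near-identical genes were not examined.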

Results

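Poly(A) RNA was sequenced from 12 libraries of adult Caenorhabditis elegans in the glp-1(e2144) background, which largely lacks a germline at the restrictive temperature. Animals carried either wild-type hoe-1 (called wild type here) or hoe-1(ΔNES), given as mpt67 in the sample titles, an allele without the nuclear export signal of HOE-1, the RNase Z (ELAC2) homologue that trims the trailing ends of precursor tRNAs in nuclei and mitochondria. Both genotypes were fed bacteria carrying a control RNAi or RNAi against atfs-1, which encodes the transcription factor of the mitochondrial unfolded protein response. Each of the 4 groups held 3 biological replicates of 800 animals.

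Library depth lay between 25733083 and 41357645 estimated counts. The replicates held 31234449, 26566223 and 35425298 counts in wild type on control RNAi, and 34574362, 41357645 and 31974865 in hoe-1(ΔNES) on control RNAi. On atfs-1 RNAi they held 32915371, 34333193 and 31506709 counts in wild type and 25733083, 34452981 and 28565227 in hoe-1(ΔNES). Of 21978 genes in the files, 13947 had enough counts to be tested. Expression is given in CPM after TMM scaling with the SD. Changes are log2 fold changes with their SE, and n = 3 libraries per group throughout.

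The first 3 principal components held 42.6%, 24.3% and 11.2% of the variance. Vitellogenin mRNAs, which encode yolk proteins, took 24.01% ± 1.593 of the counts (SD, n = 3) in wild type and 14.3% ± 2.22 in hoe-1(ΔNES) on control RNAi. They took 19.2% ± 0.897 and 15.4% ± 1.87 on atfs-1 RNAi. The 12 mRNAs of the mitochondrial genome took 1.27% ± 0.094 and 3.97% ± 0.328 of the counts on control RNAi in wild type and hoe-1(ΔNES), and 1.35% ± 0.093 and 1.87% ± 0.158 on atfs-1 RNAi.

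The targeted genes were examined first. On control RNAi atfs-1 (WBGene00013878, chromosome V, 14193663 to 14197700, Ensembl 115 annotation of WBcel235) stood at 98.7 ± 19.4 CPM in wild type and 98.7 ± 4.51 CPM in hoe-1(ΔNES). On atfs-1 RNAi it stood at 30.7 ± 2.16 CPM in wild type and 45.8 ± 7.65 CPM in hoe-1(ΔNES), a fall of atfs-1 mRNA in both genotypes (log2 fold changes -1.68 ± 0.14 and -1.11 ± 0.14; edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 3.13e-06 and 4.14e-05). The remaining atfs-1 mRNA was higher in hoe-1(ΔNES) than in wild type by 0.58 ± 0.14 (edgeR quasi-likelihood test, adjusted p = 0.00802).

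The hoe-1 gene (chromosome IV, 4739490 to 4744267) stood at 32.2 ± 3.4 CPM in wild type and 50.8 ± 5.07 CPM in hoe-1(ΔNES) on control RNAi, a rise of 0.66 ± 0.12 (edgeR quasi-likelihood test, adjusted p = 0.000397). On atfs-1 RNAi hoe-1 stood at 39.3 ± 2.34 and 48.2 ± 8.19 CPM, a difference of 0.29 ± 0.12 that did not pass the test (adjusted p = 0.077). That hoe-1 difference passed when HOE1_atfs1 replicate 1 was left out (0.37, adjusted p = 0.0461) and when libraries were scaled by total counts alone (0.44, adjusted p = 0.0157). The difference in hoe-1 between wild type on atfs-1 RNAi and on control RNAi, 0.29, was not called either (adjusted p = 0.104) and reached 0.39 with total counts (adjusted p = 0.0429).

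The mitochondrial chaperone genes hsp-6 (mtHSP70; chromosome V, 4824124 to 4826760) and hsp-60 (chromosome III, 1619742 to 1625803) are standard reporters of the mitochondrial unfolded protein response. In wild type on control RNAi hsp-6 stood at 163 ± 21.2 CPM and hsp-60 at 27.9 ± 4.07 CPM. In hoe-1(ΔNES) on control RNAi hsp-6 stood at 545 ± 53.6 CPM and hsp-60 at 131 ± 6.8 CPM. On atfs-1 RNAi hsp-6 stood at 132 ± 23.5 CPM in wild type and 124 ± 8.31 CPM in hoe-1(ΔNES), and hsp-60 at 32.4 ± 0.854 and 18.2 ± 0.858 CPM.

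**Figure D1:**
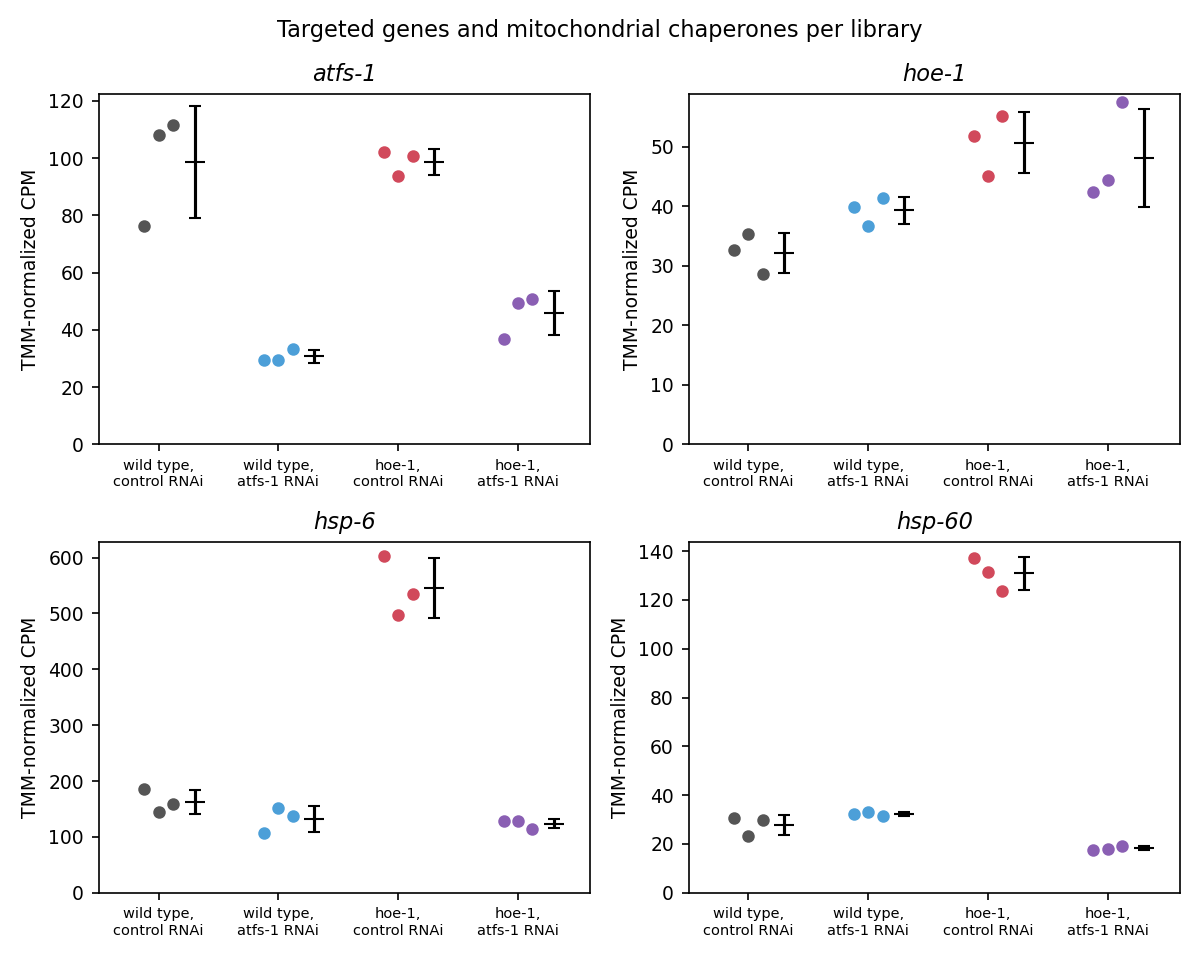
Expression of atfs-1, hoe-1, hsp-6 and hsp-60 in CPM after TMM scaling, with 1 point per library, the group mean and the SD over 3 libraries. The means of hsp-6 and hsp-60 are 545 and 131 CPM in hoe-1(ΔNES) on control RNAi, against 163 and 27.9 CPM in wild type on control RNAi and 124 and 18.2 CPM in hoe-1(ΔNES) on atfs-1 RNAi.

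The comparison of hoe-1(ΔNES) with wild type on control RNAi asked what the loss of the nuclear export signal of HOE-1 does to the transcriptome when atfs-1 is expressed. In hoe-1(ΔNES) 14 of 15 mitochondrial chaperone and protease genes, 14 of 15 import genes and 69 of 70 mitochondrial ribosomal protein genes were higher. So were all 12 mRNAs of the mitochondrial genome itself. Of these lists only the chaperones were called with an estimated correlation. Among these genes hsp-60 rose by 2.23 ± 0.10, the DnaJ homologue dnj-10 by 2.16 ± 0.10, the import channel gene timm-23 by 2.16 ± 0.11 and the mtDNA gene ND4 by 2.35 ± 0.11. Lower genes included 18 of 35 innate immune effectors and 4 of 6 yolk protein genes, among them the lysozyme gene lys-1 (2802 ± 382 CPM in wild type and 126 ± 2.35 CPM in hoe-1(ΔNES)).

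In all 2970 genes were higher and 3140 lower by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p below 0.05, of which 1071 and 837 changed at least 2-fold. For 7226 genes (51.8%) the replicates of the 2 groups did not overlap, where chance gives 10%. Scaling by total counts alone gave 5675 higher and 1534 lower and moved the median of all genes from 0.022 to 0.295. Directions given here are relative to the TMM scaling.

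Of the 15 mitochondrial chaperone and protease genes, 14 rose and 1 fell, the same counts adjusted over the list alone, with a median of 1.65 (camera adjusted p = 1.7e-21, and adjusted p = 0.0491 with an estimated correlation). The prohibitin genes phb-1 (1.65 ± 0.09) and phb-2 (1.81 ± 0.10) were in this group beside hsp-6, which rose by 1.74 ± 0.13. Of 15 tested import genes 14 rose, and 14 adjusted over the list alone, with a median of 1.30 (camera adjusted p = 1.29e-17; adjusted p = 0.109 with an estimated correlation). They included mppa-1, a subunit of the processing peptidase (2.63 ± 0.16), and tomm-70 (1.53 ± 0.10). All 12 tested mtDNA mRNAs rose, with ND1 at 1.98 ± 0.08 and CYTB at 2.00 ± 0.09, and 12 did so adjusted over the list alone. Their median was 1.84 (camera adjusted p = 7.54e-25; adjusted p = 0.109 with an estimated correlation).

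Of 70 mitochondrial ribosomal protein genes, 69 rose over all genes and 70 adjusted over the list alone, led by mrps-14 (2.33 ± 0.10) and mrpl-38 (1.26 ± 0.09). The median was 0.91 (camera adjusted p = 2.38e-26; adjusted p = 0.218 with an estimated correlation). Nuclear respiratory chain and ATP synthase genes rose by a median of 0.60, in 41 of 43 members and in 43 adjusted over the list alone (camera adjusted p = 7.51e-17, and adjusted p = 0.375 with an estimated correlation). Examples were sdha-2 of complex II (1.78 ± 0.11), cyc-1 for cytochrome c1 (0.93 ± 0.06) and gas-1 of complex I (0.89 ± 0.07). Of 22 genes of pyruvate dehydrogenase, the TCA cycle and the glyoxylate cycle, 19 rose and 1 fell, also adjusted over the list alone, with dld-1 at 0.96 ± 0.07 and fum-1 at 0.77 ± 0.07. The median of these genes was 0.50 (camera adjusted p = 8.5e-06; adjusted p = 0.382 with an estimated correlation). Of 32 aminoacyl-tRNA synthetase genes 22 rose, and 23 adjusted over the list alone, including the cytosolic lars-1 (1.40 ± 0.06) and the mitochondrial nars-2 (1.56 ± 0.14) and yars-2 (1.33 ± 0.12). Their median was 0.48 (camera adjusted p = 1.89e-07; adjusted p = 0.356 with an estimated correlation).

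Of 35 innate immune effector genes 18 fell and 5 rose, the same counts adjusted over the list alone. Besides lys-1 (-4.47 ± 0.13), the infection response genes irg-5 (467 ± 38.9 to 10.3 ± 2.95 CPM) and irg-3 (-1.63 ± 0.12) and dod-24 (-2.62 ± 0.15) fell. The median was -0.69 (camera adjusted p = 9.59e-08; adjusted p = 0.235 with an estimated correlation). In the fatty acid list 20 of 32 genes fell and 2 rose, or 21 and 3 adjusted over the list alone. The median of the list was -0.42, or -0.144 with total counts alone (camera adjusted p = 0.00293; adjusted p = 0.335 with an estimated correlation). The lipase genes lipl-5 (-1.84 ± 0.20) and lipl-1 (-2.40 ± 0.27) and the desaturase gene fat-2 (-0.57 ± 0.08) were lower, and the thiolase gene kat-1 was higher (0.61 ± 0.07).

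Of 21 genes of the unfolded protein response of the endoplasmic reticulum, 16 fell and 1 rose, also adjusted over the list alone, in contrast to the mitochondrial chaperones. Calreticulin crt-1 (-0.87 ± 0.08), pdi-3 (-0.55 ± 0.06) and the GRP94 homologue enpl-1 (-0.64 ± 0.10) were among them. The median change was -0.40, or -0.126 with total counts alone (camera adjusted p = 0.00134; adjusted p = 0.326 with an estimated correlation). Of 6 vitellogenin genes 4 fell, and 4 adjusted over the list alone, with vit-6 at -0.80 ± 0.12 and vit-5 at -2.15 ± 0.18. The vitellogenin median was -1.33 (camera adjusted p = 0.000192; adjusted p = 0.403 with an estimated correlation), and vit-3, vit-4 and vit-5 are near-identical, so the split of reads among them is uncertain. Intestine markers also moved, with 9 of 16 higher and 3 lower, the same counts adjusted over the list alone, and a median of 0.58 (camera adjusted p = 0.0174; adjusted p = 0.494 with an estimated correlation). Glycolysis genes went up in 10 of 18 cases and down in 3, or 11 and 4 adjusted over the list alone, with a median of 0.27 (camera adjusted p = 0.0341; adjusted p = 0.653 with an estimated correlation). The glycolysis call was lost without HOE1_control replicate 2 (0.057), without WT_control replicate 2 (0.0794) and with only the 2 groups compared (0.0504).

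**Figure D2:**
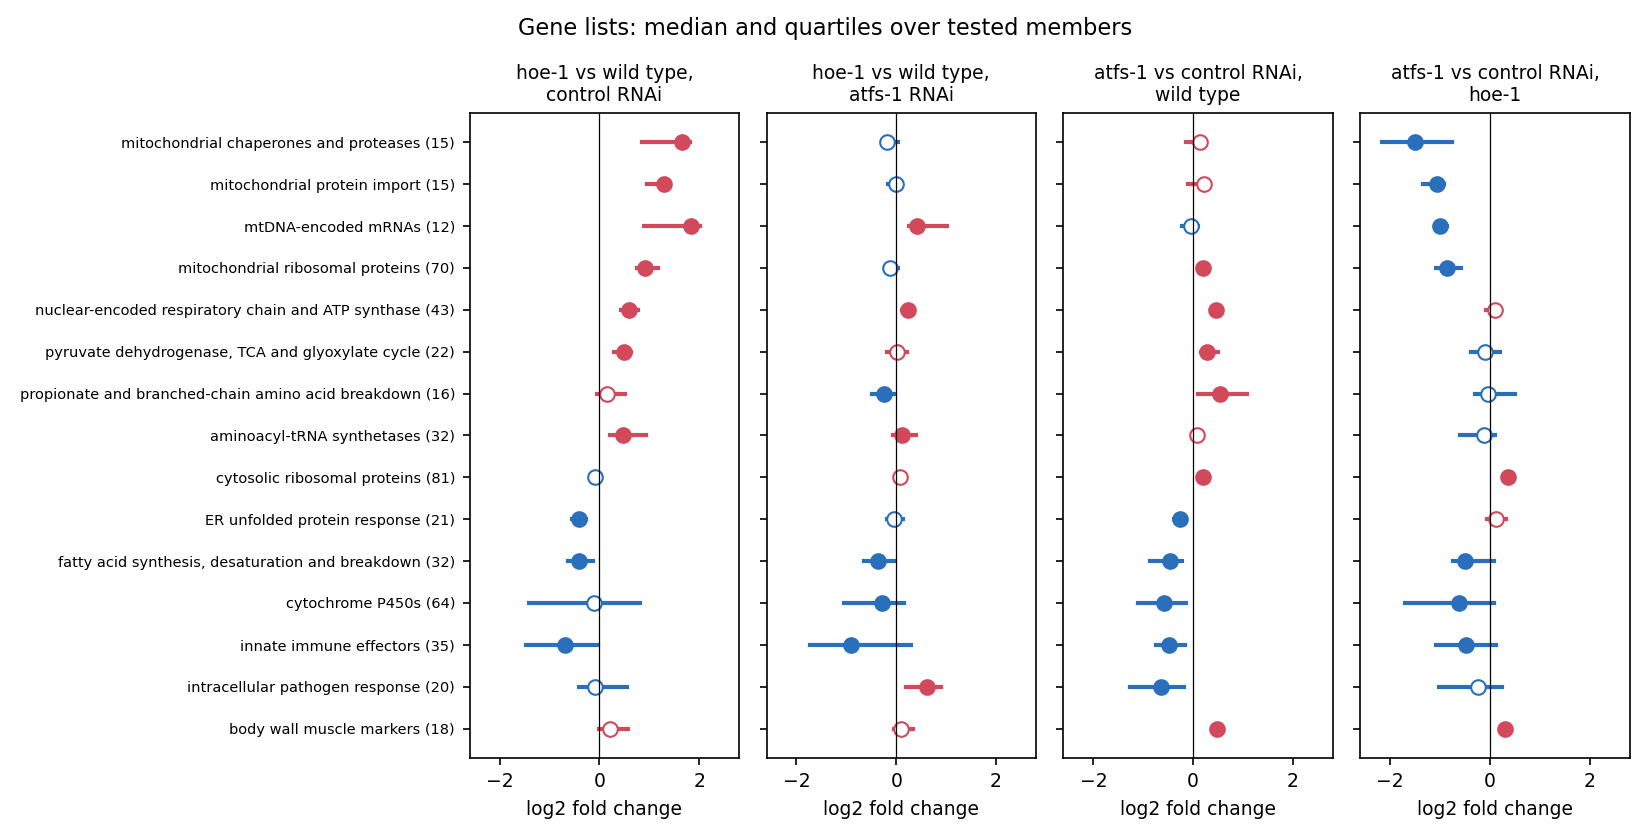
Median log2 fold change (point) and quartiles (bar) of 15 gene lists in the 4 comparisons, with filled points for lists called by camera at an adjusted p below 0.05 with the preset correlation, red for higher and blue for lower. The mitochondrial chaperones sit at 1.65 for hoe-1(ΔNES) on control RNAi and at -1.51 for atfs-1 RNAi in hoe-1(ΔNES), and the mtDNA mRNAs at 1.84 and -1.01.

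The largest single increases in hoe-1(ΔNES) on control RNAi began from almost no expression. F22B3.7 had 0 counts in the 3 wild-type libraries and 26.5 ± 5.11 CPM in hoe-1(ΔNES), at least 738-fold higher against a floor of 3 counts over the group. Such floors and intervals cover counting error only. The C-type lectin gene clec-17 went from 0.16 ± 0.0844 to 27.8 ± 4.66 CPM, and the cytochrome P450 gene cyp-14A4 rose by 5.87 ± 0.27. The gene bath-45 rose by 6.43 ± 0.38, Y111B2A.2 rose by 5.90 ± 0.29, and the pseudogene C54E10.1 went from 0.0123 ± 0.0214 to 9.9 ± 0.0972 CPM. The protease gene cpr-2 rose by 5.82 ± 1.57, a call lost without WT_control replicate 3 (5.31, edgeR quasi-likelihood test, adjusted p = 0.0643).

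Several of the genes that gained expression are known for roles in the germline. The Bicaudal-C homologue gld-3 stood at 0.0104 ± 0.018 CPM in wild type, from 1 count, and at 10.1 ± 0.955 CPM in hoe-1(ΔNES). The gene rnp-8, which like gld-3 encodes a partner of the GLD-2 poly(A) polymerase, went from 0.116 ± 0.111 to 9.56 ± 0.468 CPM and the Y-box gene cey-2 rose by 5.64 ± 0.52. Of 24 germline and oocyte markers 13 rose and 3 fell, also adjusted over the list alone, with the synaptonemal complex gene syp-1 at 4.03 ± 0.28, mex-3 at 2.15 ± 0.18 and the eggshell gene perm-4 at -1.36 ± 0.07. The median was 1.13 (camera adjusted p = 0.028; adjusted p = 0.326 with an estimated correlation). That call was also lost without HOE1_control replicate 1 (adjusted p = 0.0516), with DESeq2 (0.173), with a stricter filter on low counts (0.661) and with total counts alone (0.089).

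The largest decreases on control RNAi were those of F56A4.3 (57.6 ± 6.5 to 0.0683 ± 0.0111 CPM), the insulin-like gene ins-19 (22.1 ± 6.69 to 0.0718 ± 0.0663 CPM) and the P450 gene cyp-14A3 (145 ± 26.2 to 1.61 ± 0.398 CPM). M199.9 fell by 6.35 ± 0.21, cld-1 by 6.15 ± 0.53, C54C8.12 by 4.99 ± 0.28 and W04A4.2 by 4.99 ± 0.13. The sphingomyelinase gene asm-3 fell by 5.85 ± 0.49, and the P450 gene cyp-35A3 went from 103 ± 22.1 to 1.9 ± 0.474 CPM.

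The same genotype comparison on atfs-1 RNAi asked which of these differences are present when atfs-1 is reduced. The mitochondrial chaperone genes were no longer higher in hoe-1(ΔNES): hsp-60 was lower by 0.83 ± 0.10, and the hsp-6 difference was -0.10 ± 0.13 (edgeR quasi-likelihood test, adjusted p = 0.618). Of the 12 mtDNA mRNAs 8 were still higher and 1 was lower, with ND1 at 1.58 ± 0.08 and ND2 at 2.58 ± 0.16, the largest of them. Of 35 innate immune effectors 20 were lower and 5 higher, with lys-1 lower by 4.71 ± 0.13. The octopamine synthesis gene tbh-1 (chromosome X, 15500256 to 15504895) was at 1398 ± 102 CPM in wild type and 3.48 ± 0.286 CPM in hoe-1(ΔNES), a change of -8.65 ± 0.11.

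On atfs-1 RNAi 2067 genes were higher and 2015 lower (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), 528 and 751 of them at least 2-fold. The groups did not overlap for 6471 genes (46.4%, against 10% by chance). Total counts alone gave 3473 higher and 1364 lower, with the median of all genes moved from 0.024 to 0.169.

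Of 15 chaperone and protease genes 4 fell, or 5 adjusted over the list alone, and the list was not called. Its median was -0.18 (camera adjusted p = 0.394). Of 70 mitochondrial ribosomal protein genes 4 rose and 3 fell, or 3 rose adjusted over the list alone, and the uncalled median of -0.12 became 0.02 with total counts alone (camera adjusted p = 0.689). Of 12 mtDNA mRNAs 8 rose and 1 fell, or 9 and 1 adjusted over the list alone, with ND4 at 1.25 ± 0.11. The mtDNA median was 0.41 (camera adjusted p = 1.22e-05; adjusted p = 0.487 with an estimated correlation). Respiratory chain genes rose by a median of 0.23 in 22 of 43 members, and in 26 adjusted over the list alone, with the ATP synthase genes atp-3 at 0.51 ± 0.07 and atp-2 at 0.39 ± 0.07 (camera adjusted p = 0.0035; adjusted p = 0.755 with an estimated correlation).

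Of 35 innate immune effectors 20 fell and 5 rose on atfs-1 RNAi, or 20 and 7 adjusted over the list alone, with dod-24 at -3.61 ± 0.16, clec-67 at -2.54 ± 0.13 and the antimicrobial peptide gene abf-1 at -4.57 ± 0.30. Their median was -0.90 (camera adjusted p = 8.21e-10; adjusted p = 0.125 with an estimated correlation). Of 64 cytochrome P450 genes 22 fell and 3 rose, or 23 and 4 adjusted over the list alone, among them cyp-35A3 (-3.75 ± 0.24), with a median of -0.29 (camera adjusted p = 0.00113; adjusted p = 0.494 with an estimated correlation). Of 16 genes for the breakdown of propionate and branched-chain amino acids, 8 fell and 1 rose, also adjusted over the list alone, with the shunt genes hphd-1 at -1.27 ± 0.09, ech-6 at -0.75 ± 0.06 and hach-1 at -2.23 ± 0.17. The median of that list was -0.24 (camera adjusted p = 0.0188; adjusted p = 0.356 with an estimated correlation), and the call was lost with total counts (0.0722) and with the stricter filter (0.0568). In the intracellular pathogen response list 8 of 20 genes rose and 2 fell, or 9 and 2 adjusted over the list alone, with pals-6 at 1.36 ± 0.09. The median of the list was 0.63 (camera adjusted p = 0.0271; adjusted p = 0.335 with an estimated correlation). That call was lost without HOE1_atfs1 replicate 3 (adjusted p = 0.0515) and with the stricter filter (0.056). Of 16 intestine markers 6 rose and 1 fell, also adjusted over the list alone, with a median of 0.35 (camera adjusted p = 0.0266; adjusted p = 0.554 with an estimated correlation), a call lost with the stricter filter (0.054). Of 32 fatty acid genes 18 fell and 5 rose, or 19 and 5 adjusted over the list alone, with a median of -0.365 (camera adjusted p = 0.0247; adjusted p = 0.424 with an estimated correlation; 0.0609 with the stricter filter). Of 32 aminoacyl-tRNA synthetase genes 12 rose and 1 fell, or 13 and 1 adjusted over the list alone, with a median of 0.12 (camera adjusted p = 0.0274; adjusted p = 0.692 with an estimated correlation; 0.0523 without HOE1_atfs1 replicate 1).

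The largest increases on atfs-1 RNAi were those of sdz-35 (0.242 ± 0.157 to 11.9 ± 2.97 CPM), C36E6.8 (0.284 ± 0.0297 to 7.82 ± 1.2 CPM), B0348.2, F22E5.6 and K11H12.6, and of the lysozyme gene lys-4 (3.8 ± 0.92 to 41.4 ± 9.65 CPM). F56A4.3, M199.9, C54C8.12 and E02H9.7 had 0 counts in hoe-1(ΔNES) on atfs-1 RNAi, at least 2175.5-, 766-, 214- and 106-fold lower than in wild type. The C-type lectin gene clec-190 went from 219 ± 14.5 to 0.18 ± 0.168 CPM, and the collagen gene col-135 fell by 8.09 ± 0.27. The uterine lumen genes ule-1 to ule-5, chosen after their values were seen, were all lower in hoe-1(ΔNES) on atfs-1 RNAi, ule-1 at 1398 ± 78.3 and 56.6 ± 8.88 CPM and ule-5 at 1013 ± 44.2 and 24.1 ± 3.03 CPM.

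**Figure D3:**
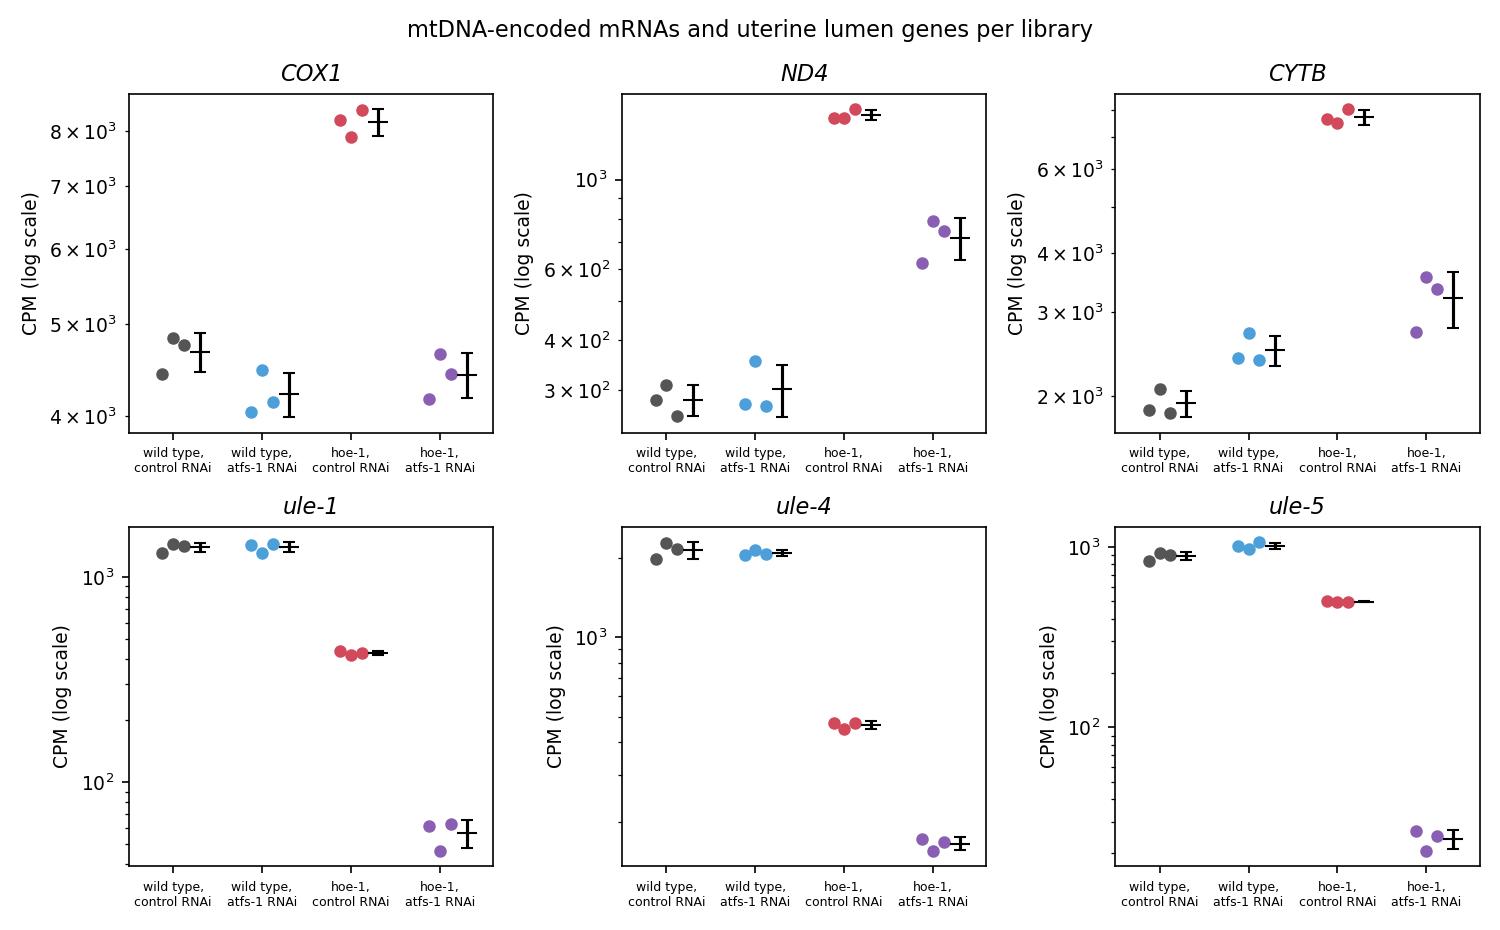
Expression of the mtDNA genes COX1, ND4 and CYTB and of the uterine lumen genes ule-1, ule-4 and ule-5 in CPM after TMM scaling on a log axis, with 1 point per library and the group mean. The ule-5 mean is 890 CPM in wild type on control RNAi and 24.1 CPM in hoe-1(ΔNES) on atfs-1 RNAi.

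Whether the genotype differences changed with atfs-1 RNAi was tested as the interaction of genotype and RNAi. The genotype difference was smaller in size on atfs-1 RNAi for hsp-60 (interaction -3.06 ± 0.14), hsp-6 (-1.84 ± 0.18), dnj-10 (-2.38 ± 0.14) and mppa-1 (-3.27 ± 0.23), and for the mtDNA gene CYTB (-1.64 ± 0.13). That of hsp-60 turned from higher to lower. For hsp-6, dnj-10 and mppa-1 the interaction was also larger in size than the rise on control RNAi. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 1900 genes had a positive and 1807 a negative interaction, with 1154 and 2384 when libraries were scaled by total counts alone, which moved the median of all genes from -0.007 to -0.135. Of 15 chaperone and protease genes 14 had a negative interaction and 1 a positive one. Their median was -1.66 (camera adjusted p = 1.11e-25, and adjusted p = 0.0351 with an estimated correlation). Of 70 mitochondrial ribosomal protein genes 65 had a negative interaction (median -1.03, camera adjusted p = 1.55e-27; adjusted p = 0.211 with an estimated correlation), as had 10 of 12 mtDNA mRNAs. For those the median was -0.88 (camera adjusted p = 1.41e-09; adjusted p = 0.335 with an estimated correlation).

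Of the 2970 genes higher in hoe-1(ΔNES) on control RNAi, 899 (30.3%) were also higher on atfs-1 RNAi, where 440.2 would be shared by chance, 171 were lower and 1900 were not called. The median log2 fold change of those genes was 0.755 on control RNAi and 0.203 on atfs-1 RNAi. Of the 3140 lower genes 1161 (37%) were also lower on atfs-1 RNAi, where 453.7 would be shared by chance, 232 were higher and 1747 were not called, with medians of -0.609 and -0.187. Simulated counts with no interaction gave medians of 0.819 and 0.729 for the higher genes and -0.67 and -0.62 for the lower ones, with 78.85% and 79.343% of them called the same way on atfs-1 RNAi. The interaction opposed the change on control RNAi for 1220 of the higher and 1291 of the lower genes, 41.1% of each. It went in the direction of the change for 67 of the higher and 214 of the lower genes. The simulations with no interaction called it for 0 genes. Across the 13947 genes, which are not independent replicates, the changes on the 2 RNAi conditions had a Pearson r of 0.455 and a Spearman rho of 0.362. The 2 comparisons share no library, and the Pearson r was 0.917 in the simulations with no interaction. Those simulations took the fitted changes, noise included, as the true ones. Their medians, shares and r may therefore overstate how alike the 2 conditions would be.

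**Figure D4:**
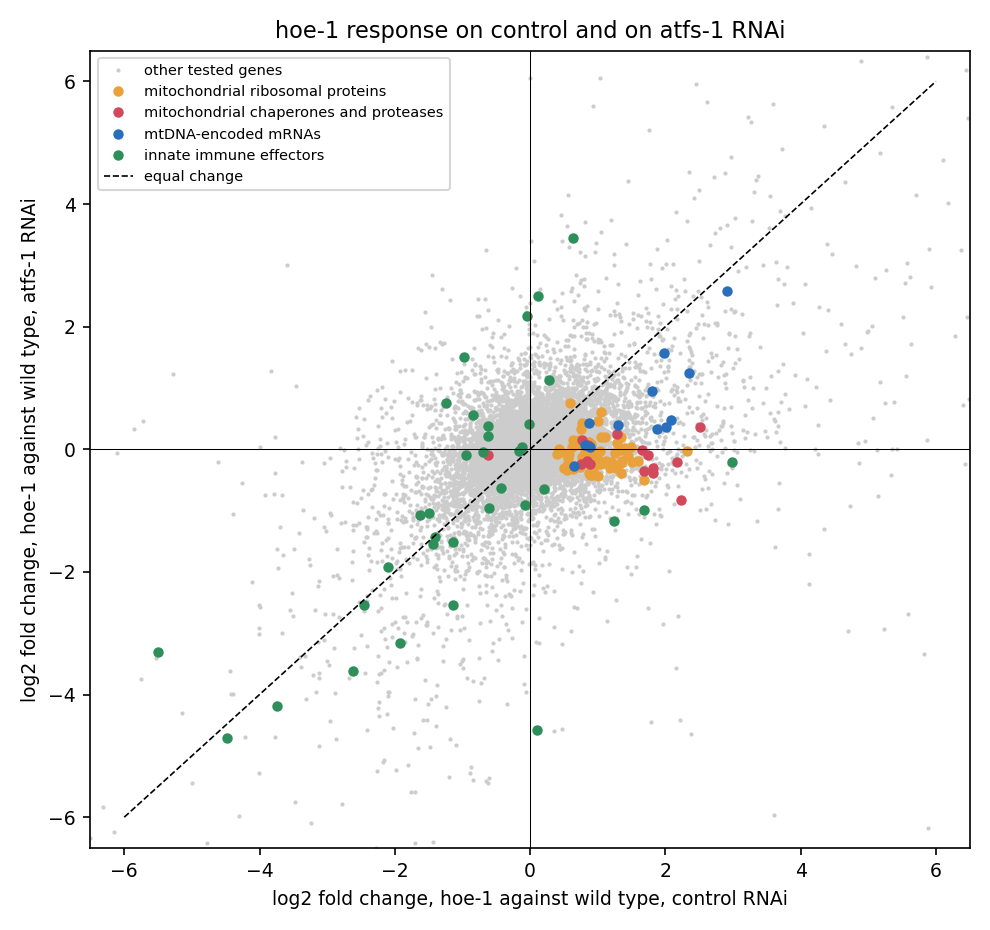
Log2 fold change of hoe-1(ΔNES) against wild type on control RNAi (horizontal axis) and on atfs-1 RNAi (vertical axis), with 1 point per tested gene, coloured lists and a dashed line of equal change. Axes end at 6.5 in either direction, which leaves 65 genes outside, and the mitochondrial chaperones lie near a vertical value of -0.18 while the immune effectors lie around -0.69 and -0.90.

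The effect of atfs-1 RNAi in wild type asked what reduced ATFS-1 changes without the hoe-1 allele. Higher genes included 40 of 43 respiratory chain genes and 11 of 16 genes of propionate and branched-chain amino acid breakdown. Lower genes included 28 of 64 cytochrome P450, 19 of 32 fatty acid and 13 of 35 innate immune genes. The propionate shunt gene hphd-1 rose by 1.83 ± 0.09, and the acyl-CoA dehydrogenase gene acdh-2 went from 4.4 ± 2.29 to 294 ± 13 CPM. The desaturase gene fat-7 fell by 3.61 ± 0.42 and the lysozyme gene lys-7 by 2.21 ± 0.11. The difference in hsp-6 was -0.30 ± 0.13 (edgeR quasi-likelihood test, adjusted p = 0.121) and that in hsp-60 was 0.22 ± 0.10 (adjusted p = 0.132), which passed with an effective length offset (0.50, adjusted p = 0.00239) and with total counts alone (0.32, adjusted p = 0.0226).

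There were 1273 higher and 1583 lower genes by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p below 0.05, 250 and 392 of them at least 2-fold, and 4948 genes (35.5%, against 10% by chance) whose groups did not overlap. Without WT_atfs1 replicate 1 the counts were 833 and 1038. With total counts alone they were 1958 and 1018, and the median of all genes moved from 0.005 to 0.11.

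Of 43 respiratory chain genes 40 rose, and 42 adjusted over the list alone, with sdha-2 at 1.09 ± 0.10 and atp-2 at 0.76 ± 0.07. The respiratory chain median was 0.45 (camera adjusted p = 1.77e-22; adjusted p = 0.335 with an estimated correlation). Of 16 propionate and branched-chain genes 11 rose, or 11 with 1 lower adjusted over the list alone, including ech-6 (1.01 ± 0.06) and alh-8 (0.94 ± 0.06), with a median of 0.53 (camera adjusted p = 5.13e-19, and adjusted p = 0.0249 with an estimated correlation). Body wall muscle markers were higher in 17 of 18 cases, also adjusted over the list alone, with paramyosin unc-15 at 0.51 ± 0.06 and actin act-4 at 0.53 ± 0.07. The muscle median was 0.48 (camera adjusted p = 4.68e-09; adjusted p = 0.346 with an estimated correlation). Of 81 cytosolic ribosomal protein genes 43 rose, and 60 rose with 1 lower adjusted over the list alone, with rps-0 at 0.36 ± 0.06. The median change was 0.20 (camera adjusted p = 8.47e-08; adjusted p = 0.653 with an estimated correlation). Of 22 pyruvate dehydrogenase, TCA and glyoxylate cycle genes 11 rose, and 12 adjusted over the list alone, with a median of 0.27 (camera adjusted p = 1.26e-06; adjusted p = 0.347 with an estimated correlation). Mitochondrial ribosomal protein genes had a median of 0.20, with 8 of 70 higher and 4 adjusted over the list alone (camera adjusted p = 0.000964; adjusted p = 0.685 with an estimated correlation; 0.0693 without WT_control replicate 3). Glycolysis genes were higher in 9 of 18 cases, also adjusted over the list alone, with a median of 0.16 (camera adjusted p = 0.0251; adjusted p = 0.653 with an estimated correlation), a call lost without WT_control replicate 2 (0.0794) and with the stricter filter (0.0568). Cuticle collagens had 19 higher, 5 lower and 80 not called, or 21 and 8 adjusted over the list alone, and a median of 0.22 (camera adjusted p = 0.0174; adjusted p = 0.653 with an estimated correlation; 0.0545 without WT_control replicate 2). Pharynx markers were called with 2 of 12 higher, or 1 adjusted over the list alone, and a median of 0.16 (camera adjusted p = 0.0157; adjusted p = 0.346 with an estimated correlation). The chaperone and protease list was not called, with 3 higher and 1 lower. Its median was 0.13 (camera adjusted p = 0.557).

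Of 64 P450 genes 28 fell and 4 rose in wild type, or 31 and 4 adjusted over the list alone, with cyp-35A3 at -2.44 ± 0.19. The P450 median was -0.59 (camera adjusted p = 3.2e-08; adjusted p = 0.326 with an estimated correlation). Of 32 fatty acid genes 19 fell and 1 rose, or 23 and 1 adjusted over the list alone, with maoc-1 at -0.62 ± 0.06, while kat-1 rose by 1.47 ± 0.07. The fatty acid median was -0.46 (camera adjusted p = 1.79e-07; adjusted p = 0.109 with an estimated correlation). Of 35 innate immune effectors 13 fell and 3 rose, or 15 and 3 adjusted over the list alone, with irg-3 at -1.04 ± 0.12. The median change was -0.48 (camera adjusted p = 1.85e-06; adjusted p = 0.291 with an estimated correlation). Of 20 intracellular pathogen response genes 8 fell, or 11 adjusted over the list alone, including pals-6 (-0.93 ± 0.10) and skr-5 (-1.21 ± 0.18), with a median of -0.64 (camera adjusted p = 7.89e-05; adjusted p = 0.109 with an estimated correlation). Of 21 genes of the unfolded protein response of the endoplasmic reticulum 10 fell and 1 rose, or 13 and 1 adjusted over the list alone, with a median of -0.27 (camera adjusted p = 0.00115; adjusted p = 0.326 with an estimated correlation). Of 6 vitellogenin genes 4 fell, and 4 adjusted over the list alone, with a median of -0.38 (camera adjusted p = 0.0407; adjusted p = 0.653 with an estimated correlation). The vitellogenin call was lost with fry (0.0506), a replicate block (0.0623) and the stricter filter (0.0833). It was also lost without WT_control replicate 1 (0.138) or 3 (0.0567), WT_atfs1 replicate 2 (0.0674) or 3 (0.0534) or HOE1_atfs1 replicate 3 (0.0535).

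The largest increases with atfs-1 RNAi in wild type were those of try-13 (0.805 ± 0.316 to 126 ± 4.23 CPM), F54E4.2 (0.362 ± 0.0941 to 42.6 ± 2.68 CPM), C09B8.4 (1.39 ± 0.5 to 127 ± 7.38 CPM), acdh-2, F54D8.10 and the glucuronosyltransferase gene ugt-32 (4.99 ± 0.834 to 120 ± 8 CPM). Among the largest decreases were C50F7.5 (248 ± 32 to 17.9 ± 4.16 CPM), cyp-14A3 (145 ± 26.2 to 10.6 ± 6.92 CPM), kreg-1 (-3.73 ± 0.35) and clec-82 (-3.31 ± 0.52). The fall of clx-1 was 3.89 ± 0.84 and became -2.72 without WT_control replicate 3.

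In hoe-1(ΔNES) the effect of atfs-1 RNAi asked which part of the mutant's expression pattern depends on atfs-1. On atfs-1 RNAi 14 of 15 mitochondrial chaperone and protease genes, 15 of 15 import genes and 64 of 70 mitochondrial ribosomal protein genes were lower. So were 12 of 12 mtDNA mRNAs. Of these lists only the chaperones were called with an estimated correlation. Among these genes hsp-60 fell by 2.85 ± 0.10, hsp-6 by 2.14 ± 0.13, mppa-1 by 2.99 ± 0.16 and ATP6 by 1.41 ± 0.09. The P450 gene cyp-14A4 fell by 6.35 ± 0.28 and the fission gene drp-1 by 1.31 ± 0.13. Of 81 cytosolic ribosomal protein genes 72 were higher, such as rla-0 (0.54 ± 0.07), as were 16 of 32 autophagy and lysosome genes, such as the autophagy receptor gene sqst-1 (1.19 ± 0.09).

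In this comparison 2336 genes were higher and 2435 lower (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), 413 and 977 of them at least 2-fold, and 6680 genes (47.9%, against 10% by chance) had groups that did not overlap. Of the 1273 genes higher with atfs-1 RNAi in wild type 510 were also higher in hoe-1(ΔNES), where 213.2 would be shared by chance, and 203 were lower (222.3 by chance). Of the 1583 lower genes 465 were also lower (276.4 by chance) and 251 were higher (265.1 by chance). The Pearson r between the 2 effects of atfs-1 RNAi was 0.135 across genes.

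Of 15 chaperone and protease genes 14 fell, and 14 adjusted over the list alone, with dnj-10 at -2.56 ± 0.10. Their median was -1.51 (camera adjusted p = 1.55e-27, and adjusted p = 0.0351 with an estimated correlation). All 15 tested import genes fell, and 15 adjusted over the list alone, with tomm-70 at -2.24 ± 0.11 and timm-17B.1 at -1.40 ± 0.08. The import median was -1.07 (camera adjusted p = 4.14e-17; adjusted p = 0.109 with an estimated correlation). All 12 mtDNA mRNAs fell, and 12 adjusted over the list alone, with COX1 at -0.89 ± 0.07 and CYTB at -1.26 ± 0.09. The mtDNA median was -1.01 (camera adjusted p = 8.82e-14; adjusted p = 0.249 with an estimated correlation). Of 70 mitochondrial ribosomal protein genes 64 fell, and 66 adjusted over the list alone, with mrps-14 at -1.59 ± 0.09. The median change was -0.87 (camera adjusted p = 1.75e-22; adjusted p = 0.27 with an estimated correlation). The list of regulators of the mitochondrial response and other reported ATFS-1 targets had 8 lower and 1 higher of 20, also adjusted over the list alone. Its median was -0.16 (camera adjusted p = 0.00288, and adjusted p = 0.109 with an estimated correlation). For hoe-1(ΔNES) against wild type on control RNAi this list was not called, with 6 higher and 5 lower (median 0.13, camera adjusted p = 0.224). Nor was it called for the interaction (camera adjusted p = 0.108).

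Of 81 cytosolic ribosomal protein genes 72 rose and 1 fell, or 77 and 2 adjusted over the list alone, with rpl-10 at 0.46 ± 0.06. The median change was 0.37 (camera adjusted p = 1.98e-12; adjusted p = 0.572 with an estimated correlation). Of 32 autophagy and lysosome genes 16 rose, and 18 adjusted over the list alone, with cathepsin L cpl-1 at 0.91 ± 0.07 and atg-16.2 at 0.75 ± 0.06. The median change was 0.20 (camera adjusted p = 0.000679; adjusted p = 0.202 with an estimated correlation). Of 64 P450 genes 34 fell and 4 rose, or 34 and 5 adjusted over the list alone, with cyp-13A12 at -6.39 ± 0.39. The P450 median was -0.63 (camera adjusted p = 2.76e-06; adjusted p = 0.346 with an estimated correlation). Of 35 innate immune effectors 16 fell and 5 rose, or 17 and 5 adjusted over the list alone, with abf-1 at -4.02 ± 0.30 and lys-2 at -0.99 ± 0.07. The immune effector median was -0.49 (camera adjusted p = 0.000248; adjusted p = 0.346 with an estimated correlation). Of 18 body wall muscle markers 13 rose, and 14 adjusted over the list alone, with a median of 0.30 (camera adjusted p = 0.00293; adjusted p = 0.653 with an estimated correlation). Of 32 fatty acid genes 16 fell and 4 rose, or 17 and 4 adjusted over the list alone, with a median of -0.50 (camera adjusted p = 0.013; adjusted p = 0.371 with an estimated correlation). Of 18 glycolysis genes 8 fell and 1 rose, or 10 and 1 adjusted over the list alone, with a median of -0.19 (camera adjusted p = 0.0231; adjusted p = 0.653 with an estimated correlation; 0.0625 without HOE1_atfs1 replicate 3). Respiratory chain genes were split, with 12 higher and 8 lower of 43, and the list was not called. Its median was 0.09 (camera adjusted p = 0.431).

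The genes with the largest decreases on atfs-1 RNAi in hoe-1(ΔNES) included several that had gained expression on control RNAi. F22B3.7 had 0 counts on atfs-1 RNAi, at least 834-fold lower. The gene gld-3 went from 10.1 ± 0.955 to 0.0347 ± 0.0359 CPM, C54E10.1 from 9.9 ± 0.0972 to 0.031 ± 0.0326 CPM, and clec-17 from 27.8 ± 4.66 to 0.158 ± 0.0127 CPM. The gene bath-45 fell by 7.82 ± 0.43. The largest increases were those of the pseudogene Y19D10B.4 (5.08 ± 0.22), F54E4.2 (4.97 ± 0.24), kin-5 (4.95 ± 0.28), sdz-35 (4.83 ± 0.38) and F22E5.6 (4.17 ± 0.27), and of asm-3, which went from 2.08 ± 1.29 to 52.5 ± 24.4 CPM.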

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

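The tests of the 3 patterns weighed here were chosen only after the result was seen, and those that split the libraries into other groups were chosen before. The interaction of genotype and RNAi, by which each result in this part stands out, was called for 1900 genes upward and 1807 downward by edgeR's quasi-likelihood test. Of 100 drawn splits of the RNAi labels within each genotype, out of 200 possible, 2 called as many genes, the real one with 3707 and another with 4312, so chance can be excluded only as far as such splits measure it. Splits that mix the RNAi conditions carry the RNAi effects in their spread, and 80 of the 100 called 0 genes with edgeR, which makes the share a weak measure for an interaction. The other split swaps all RNAi labels within 1 genotype and so measures the sum of the RNAi effects, and the next highest called 1869. For the 4 comparisons of 3 against 3 libraries the 10 possible splits are too few for a share under 0.05: the real split called 6110, 4082, 2856 and 4771 genes with edgeR and the highest other called 0 in each.

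The 12 mtDNA mRNAs were higher in hoe-1(ΔNES) than in wild type on control RNAi, by a median of 1.84, and the interaction median was -0.88 (adjusted p = 0.335 with an estimated correlation). A shift in the counts taken by a few abundant genes would move the other genes alike and is argued against as the whole cause, since with total counts alone the median of all genes was 0.295 (quartiles -0.045 and 0.668), against 2.117 for the mtDNA mRNAs. Weaker poly(A) selection would raise the replication-dependent histone mRNAs, which carry no poly(A) tail, but 8 expressed histone genes had a median of -0.34 (SD 1.07 over genes). Over all 21 tested histone genes the median was 0.09 (SD 1.57, 7 higher and 3 lower), and these near-identical genes with few counts are weak evidence. A change in mtDNA transcript amount or stability in the mutant may stand behind it, and mtDNA copy number was not measured here.

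The uterine lumen genes ule-1 to ule-5, chosen after their values were seen, were all lower in hoe-1(ΔNES), by a median of -1.71 on control RNAi and -3.65 on atfs-1 RNAi, and all 5 had a negative interaction (median -1.58). In wild type atfs-1 RNAi left their median at 0.00 and edgeR called none of them; ule-4 stood at 2134 ± 153 CPM in wild type on control RNAi and 166 ± 8.97 CPM in hoe-1(ΔNES) on atfs-1 RNAi. Larval animals among those collected would raise molting genes, whose median on atfs-1 RNAi was -0.35 (2 higher and 4 lower of 22). On control RNAi the molting median was 0.12, with 6 higher and 4 lower. The molting list alone cannot exclude larvae. On atfs-1 RNAi the collagen gene col-119 was lower in hoe-1(ΔNES) (-0.57 ± 0.07, edgeR quasi-likelihood test, adjusted p = 2.23e-05). The collagen gene col-19 was not called there (-0.22 ± 0.09), and both were chosen after their values were seen. Loss of the somatic gonad as a whole would lower lim-7, fkh-6, ipp-5 and sth-1 alike. On atfs-1 RNAi, however, 3 of these 4 kept a log2 fold change above -1 (fkh-6 -0.41, ipp-5 -0.03, sth-1 -0.01) and lim-7 fell by 1.37 ± 0.17. A delay or defect in the late differentiation of the uterus and sheath in hoe-1(ΔNES), larger on atfs-1 RNAi, may account for it and was not tested.

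Germline-type genes were detected in hoe-1(ΔNES) on control RNAi, with gld-3 at 10.1 ± 0.955 CPM against 0.0104 ± 0.018 CPM in wild type. Germ cells remaining in these animals cannot be told apart from expression elsewhere. Against them, 0 of the 2 abundant germ cell transcripts that were below the level of gld-3 in wild type rose by that level, pgl-1 (0.0136 to 0.22 CPM) and pgl-3 (0.0682 to 0.16 CPM), but 2 are few, and their level in germ cells beside gld-3 is not in these data. Another 3, glh-1 (10.4 to 17.5 CPM), car-1 (72.8 to 81.1 CPM) and cgh-1 (39.3 to 35.9 CPM), start too high for that test to decide. Of these glh-1 was called higher in hoe-1(ΔNES) on control RNAi (0.75 ± 0.10) and on atfs-1 RNAi (0.70 ± 0.10). The gene car-1 was called higher only on atfs-1 RNAi (0.26 ± 0.08) and cgh-1 on neither. For germ cells stand 13 of 24 tested germline markers that rose and 3 that fell. On atfs-1 RNAi 7 of these markers were higher in hoe-1(ΔNES) and 3 lower (median 0.36). With atfs-1 RNAi in hoe-1(ΔNES) 11 fell and 5 rose (median -1.09), as gld-3 and rnp-8 did fall, though camera did not call the list (adjusted p = 0.19). Of 29 tested sperm markers 15 rose and 5 fell (median 1.12), and on atfs-1 RNAi 12 rose and 4 fell (median 1.36). The lists hold 34 and 74 genes, and a gene can pass the filter through 1 group alone, so these shares leave out members near 0 counts. Unlike gld-3 and rnp-8, the sperm list did not fall with atfs-1 RNAi in hoe-1(ΔNES), where 2 were higher and 3 lower (median -0.08). The sperm markers, higher in hoe-1(ΔNES) on both RNAi conditions, leave germ cells in these animals possible. They do not settle the source of these 2 genes. Camera did not call the sperm list on control RNAi (adjusted p = 0.178, or 0.653 with an estimated correlation). With the preset correlation it did so with no filter (0.0106) and at 0.0261 to 0.0479 without HOE1_atfs1 replicate 2, HOE1_control replicate 2 or 3, or WT_atfs1 replicate 1, 2 or 3. A DNA variant of the strain that raises the genes whatever the level of atfs-1 is argued against for 2 of the 3 genes. These are gld-3 and rnp-8, which fell by 8.15 ± 0.51 and 5.10 ± 0.39 in the same strain on atfs-1 RNAi. A variant whose effect needs atfs-1 would give the same fall and stays open. Either kind stays open for cey-2, which fell by 1.32 ± 0.35 and was still higher than in wild type there by 1.71 ± 0.40. A further gene, cpr-2 (6.34 ± 0.742 to 0.243 ± 0.164 CPM in the same strain), was taken out of this group after its test because its germline role is uncertain.

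For gene lists the median interaction was -1.66 for mitochondrial chaperones (adjusted p = 0.0351 with an estimated correlation), -1.19 for protein import (0.109), -1.03 for mitochondrial ribosomal proteins (0.211) and -0.37 for the respiratory chain (0.641), with the p for each list in parentheses that with an estimated correlation. It was -0.58 for propionate breakdown (0.112), -0.44 for the TCA cycle list (0.494), -0.45 for glycolysis (0.424), -0.25 for aminoacyl-tRNA synthetases (0.653), -0.35 for the oxidative stress list (0.346) and -0.46 for cuticle collagens (0.554). It was 0.44 for the unfolded protein response of the endoplasmic reticulum (0.326), 0.22 for autophagy and lysosome (0.351), 0.16 for cytosolic ribosomal proteins (0.799) and -0.13 for glucuronosyltransferases (0.627). With the preset correlation the glucuronosyltransferase call was lost without HOE1_atfs1 replicate 1 (0.0965), WT_atfs1 replicate 3 (0.0738), WT_control replicate 1 (0.117) or WT_control replicate 2 (0.0794), and that of the cytosolic ribosomal proteins without WT_control replicate 1 (0.0901) and with total counts (0.109). The autophagy call was lost with total counts (0.096) and with the stricter filter (0.107).

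The interaction was -3.06 ± 0.14 for hsp-60 and -1.84 ± 0.18 for hsp-6. For atfs-1 itself it was 0.57 ± 0.20 (edgeR quasi-likelihood test, adjusted p = 0.0485), a call lost in 10 of 12 leave-one-out fits (0.48 to 0.64; without WT_control replicate 2 adjusted p = 0.129). It was kept without HOE1_atfs1 replicate 1 (adjusted p = 0.0114) and without WT_control replicate 1 (0.00565), and lost with total counts alone (0.15) and with the effective length offset (0.13). It was positive for asm-3 (6.18 ± 0.62), sdz-35 (4.67 ± 0.88), Y19D10B.4 (4.03 ± 0.28), T23F11.6 (3.79 ± 0.45) and pud-4 (3.71 ± 0.63), and for ins-19 (3.69 ± 0.95), whose call was lost without HOE1_atfs1 replicate 3 (2.97, adjusted p = 0.0695). It was negative for clec-17 (-7.34 ± 0.72) and bath-45 (-6.67 ± 1.33), the latter not without WT_atfs1 replicate 3 (-4.87, adjusted p = 0.164). For cpr-2 it was -9.16 ± 2.14, and -4.79 without WT_atfs1 replicate 2, the only library of its group with more than a trace of cpr-2 (6.89 CPM). The fitted values for gld-3 (-9.99), C54E10.1 (-9.28) and E02H9.7 (-7.5) rest on groups with 3 counts or fewer and are no bound. The calls of gld-3 and C54E10.1 were lost without WT_atfs1 replicate 3 (-6.1, adjusted p = 0.972) and WT_atfs1 replicate 1 (-6.08, adjusted p = 0.974).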

How the results depend on the processing

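All alternatives but 1 were chosen before the data were examined, and leaving the vitellogenin genes out of the scaling was chosen after seeing the data. Across them no call of a named gene or list reversed: 16 sign changes concerned genes called in neither fit. With total counts alone the direction with more genes called turned for hoe-1(ΔNES) on control RNAi. It also turned for atfs-1 RNAi in wild type and for the interaction. Of 692 pairs of a named gene and a contrast, 691 kept their side of the threshold with DESeq2 and 690 with RLE size factors. Total counts alone ended 34 calls and made 3, and the effective length offset ended 5 and made 1. Leaving out 1 library ended 287 of 8304 and made 2. The numbers of genes called with DESeq2 were 2964 higher and 3213 lower for hoe-1(ΔNES) on control RNAi, 2070 and 2201 on atfs-1 RNAi, 1362 and 1723 for atfs-1 RNAi in wild type, 2312 and 2556 in hoe-1(ΔNES), and 1986 and 1974 for the interaction. With replicate number as a block they were 3024 and 3178, 2097 and 2068, 1325 and 1607, 2402 and 2456, and 1973 and 1862.

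Total counts alone gave 5675 higher and 1534 lower on control RNAi, 3473 higher on atfs-1 RNAi, 1958 higher and 1018 lower for atfs-1 RNAi in wild type, 1154 higher for the interaction, and 2182 higher and 663 lower on both RNAi conditions. By construction this scaling ignores the shift in composition that TMM removes. The sign of 21 of 99 uncalled list medians turned with it, and that of 0 of 66 called ones. The Pearson r between the genotype effects, 0.455, was 0.276 with no filter, 0.506 with only the groups compared, 0.478 with the stricter filter and 0.405 to 0.467 leaving out 1 library. The Spearman rho, 0.362, was 0.263 with no filter and 0.336 to 0.381 leaving out 1 library; the cause was not tested. Leaving out 1 library gave 833 to 1298 higher and 1038 to 1600 lower genes for atfs-1 RNAi in wild type, the lowest of each without WT_atfs1 replicate 1; the cause was not tested. Of 66 list calls 4 held with an estimated correlation, and fry, which does not compare a list with other genes, called 114.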

Other observations

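Apart from tbh-1, which the naming rule takes on atfs-1 RNAi, the genes of this paragraph and of the last one were chosen after their values were seen, and no explanation was tested for any of them. Several genes lost most of their expression in hoe-1(ΔNES) and nearly all of it when atfs-1 RNAi was added. The octopamine synthesis gene tbh-1 went from 1999 ± 158 CPM in wild type on control RNAi to 144 ± 1.21 CPM in hoe-1(ΔNES) on control RNAi and 3.48 ± 0.286 CPM in hoe-1(ΔNES) on atfs-1 RNAi, with 1398 ± 102 CPM in wild type on atfs-1 RNAi. The peroxidase gene skpo-1 stood at 456 ± 41.7, 21.5 ± 1.68, 3.2 ± 0.524 and 489 ± 55.4 CPM in the same order, and ZK813.2 at 425 ± 35.5, 62 ± 0.404, 1.95 ± 0.343 and 485 ± 7.03 CPM. The interaction was called for tbh-1 (-4.86 ± 0.12), skpo-1 (-2.86 ± 0.17) and ZK813.2 (-5.16 ± 0.13). The C-type lectin gene clec-223 stood at 184 ± 21.4 CPM in wild type and 142 ± 7.28 CPM in hoe-1(ΔNES) on control RNAi, and at 1.83 ± 0.495 CPM in hoe-1(ΔNES) on atfs-1 RNAi (interaction -6.43 ± 0.21).

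In hoe-1(ΔNES) on control RNAi, of 15 tested genes of mitochondrial dynamics, mitophagy and mtDNA upkeep 8 rose, and 8 adjusted over the list alone, with the mtDNA polymerase gene polg-1 at 1.02 ± 0.12 and the cristae gene immt-1 at 0.57 ± 0.07 (camera adjusted p = 0.0141; adjusted p = 0.434 with an estimated correlation). The oxidative stress list went both ways on control RNAi, with 11 of 26 genes higher and 6 lower, and was not called (camera adjusted p = 0.149). Its higher genes included trxr-2 (1.37 ± 0.13), prdx-3 (0.97 ± 0.09), sod-2 (0.83 ± 0.08) and gst-6 (0.94 ± 0.11), and its lower genes mtl-1 (-1.58 ± 0.24) and sod-4 (-0.57 ± 0.09), the last 2 chosen after their values were seen. The interaction was negative for prdx-3 (-1.16 ± 0.13) and sod-2 (-0.97 ± 0.12), as it was for 11 of 26 genes of that list against 3 that were positive (camera adjusted p = 0.00677; adjusted p = 0.346 with an estimated correlation).

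The gene glf-1 lies on chromosome IV (5885835 to 5889821), as hoe-1 does. It was detected in wild type (3.29 ± 0.129 CPM on control RNAi and 2.84 ± 0.266 CPM on atfs-1 RNAi). In hoe-1(ΔNES) glf-1 was at 0.0249 ± 0.0234 and 0.0201 ± 0.0176 CPM, where 3 counts or fewer per group give no interaction to judge. The cuticle collagen gene col-119 was at 5139 ± 136, 5297 ± 132, 6330 ± 118 and 4257 ± 455 CPM in wild type on control RNAi, the mutant on control RNAi, wild type on atfs-1 RNAi and the mutant on atfs-1 RNAi.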
